A study of Mus musculus with 7 samples.

How the data were processed

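Expression was measured on an Illumina mouse BeadChip with 25697 probes in 7 whole-lung RNA samples from embryos at embryonic day 18, all on 1 chip. The labels name 4 samples Grp78f/f (replicates 2, 12, 7-2 and 7-1) and 3 samples cGrp78f/f (replicates 5, 4 and 6), each from a separate embryo, and the replicate numbers pair no samples across the groups. The deposited intensity values are average bead signals per probe, per the column headers, and were deposited as non-normalised. Their array medians, between 284 and 324, are those of a linear scale. The submitters' processing notes name BeadStudio without a version, and background subtraction is not given in the sources used here. The deposited detection p-values, 1 p-value per probe and array, compare each probe with the array's negative control beads, per the file headers. The authors also deposited a table of log2-like values, for which the submitters' processing notes name BeadStudio and lumi without versions. All 7 of its columns held the same set of values, with a median of 8.17, as quantile normalisation gives; the exact transform is not given in the sources used here. With each probe's mean over the arrays subtracted, the quantile-normalised log2 signals of each array correlated across probes with its own column of that table at 0.991 to 0.993 and with no other column above 0.425; probes are not independent replicates.

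The non-normalised signals were processed in R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0. Background was corrected by the normexp model, with the negative control distribution inferred from the detection p-values and an offset of 16, followed by quantile normalisation between arrays and log2. Probes with a detection p under 0.05 on at least 3 arrays were kept, 14994 in all. Of all probes, 23978 carried a single gene symbol and 1719 were left unnamed; 23962 of the named probes were found in the reference annotation, which was used for names only. For each gene the probe with the highest mean level was tested, and unnamed probes were tested under their own identifiers, which gave 11035 tested genes, 877 of them unnamed. The number of arrays limits the precision of each value.

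The comparison was 3 arrays labelled cGrp78f/f minus 4 arrays labelled Grp78f/f, with limma's linear model and moderated test, Benjamini-Hochberg adjustment and an adjusted p under 0.05. Hspa5 was also tested by an exact two-sided permutation of the difference of means over all 35 splits. A total of 23 gene lists, each described in the results, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Member counts were taken over all tested genes and also adjusted over the list alone. The genes named were Hspa5, the 12 with the largest positive and the 12 with the largest negative difference among passing genes whose groups did not overlap, and in each list up to 4 members with the smallest p. This gave 112 genes, of which 42 passed; 33 had several tested probes, and in 3 of these, Gstm1, Sntn and Slc26a9, the probes differed in sign. Sex was read from Xist and Y-linked probes. Where a gene was not above background on any array of a group, its difference is a lower bound under this background correction, taken against the lowest detected level of each of those arrays where the gene lay under it.

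The groups, test, lists, naming rule and most other settings were fixed before the data were examined. The settings fixed in this way were an offset of 50 without control probes, no background correction, cyclic loess, median scaling, the authors' value table, no filter on dim probes, a detection p under 0.01 on all arrays, all probes counted, each replicate left out, control replicates 7-1 and 7-2 averaged, array position or embryo sex as a covariate, eBayes with trend and robust, array weights, at least 1.5-fold, and an adjusted p under 0.01. Chosen after the data were seen were the omission of both control arrays numbered 7, the omission of the pair of arrays with the highest Nppa, and the mean level of heart muscle genes as a covariate, from a list of 18 genes of which 15 were tested. The pipeline was tested on simulated data with 11035 genes, 200 of them changed, and 3 against 4 arrays. It recovered 0 of 50 genes changed by a log2 of 0.5, 38 of 50 at 1, 50 of 50 at 2 and 50 of 50 at 4, with 1 false call among 139 calls, and 4 of 100 unchanged lists had a camera p under 0.05. The simulated genes varied independently of each other. The share of unchanged lists therefore says nothing about lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sample was left out of the comparison.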

Results

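Whole lungs of mouse embryos of mixed strain background were taken at embryonic day 18, and the RNA of each lung was measured on an Illumina BeadChip with 25697 probes. The labels put 4 lungs in the group Grp78f/f, the control here, and 3 lungs in the group cGrp78f/f, whose titles carry the letters KO. GRP78, also called BiP, is the main Hsp70-type chaperone of the endoplasmic reticulum (ER) and is the product of the gene Hspa5. The study's title places the comparison in the question of how GRP78 serves the ER and the survival of epithelium in the developing lung. The median signal of the arrays lay between 284 and 324 intensity units, and between 14445 and 15070 probes per array were detected, 56.2% to 58.6% of all probes. Across genes, the correlation of normalised levels was 0.976 to 0.987 between control lungs, 0.978 to 0.988 between the lungs labelled cGrp78f/f, and 0.947 to 0.980 between lungs of different groups; genes are not independent replicates. The control lungs numbered 7-1 and 7-2, which the labels count as separate mice, correlated at 0.979, within the range of the control pairs, and were kept as separate samples. That correlation cannot show that they are independent, and the labels do not say what the shared number 7 stands for. The tests treat them as independent. With these lungs averaged, 244 genes passed an adjusted p of 0.05 in limma. The first principal component held 46.1% of the variance, with the 3 lungs labelled cGrp78f/f between 18.5 and 33.9 on it and the 4 control lungs between -35.8 and -5.70. From Xist, which silences an X chromosome in females, and the Y-linked Eif2s3y, 1 lung of each group came from a male. Transcripts of heart muscle differed strongly between lungs. Nppa, which encodes atrial natriuretic peptide, had a log2 level of 14.14 in lung 6 labelled cGrp78f/f and 13.85 in control lung 2, against 9.80 in lung 4 and 6.12 in lung 5 labelled cGrp78f/f and 5.35 to 5.44 in the other control lungs.

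Hspa5 itself was higher, not lower, in the lungs labelled cGrp78f/f. Its log2 level was 11.69, 11.61 and 11.57 in lungs 5, 4 and 6 of that group, a mean of 11.62 ± 0.06 (SD, n = 3). In control lungs 2, 12, 7-2 and 7-1 it was 9.53, 9.33, 9.56 and 9.56, a mean of 9.50 ± 0.11 (SD, n = 4). The difference of 2.12 ± 0.11 (SE) corresponded to 4.36-fold, with an adjusted p of 3.98e-05 in limma and an exact two-sided permutation p of 0.0286, the smallest that the 35 splits of 7 lungs can give. The array carries 1 probe for Hspa5 (ILMN_1255561), and its place relative to any deleted part of the gene is not given in the sources used here, so its level checks nothing about the knockout. Because the level goes against what a knockout label would lead one to look for, the groups are named throughout as labelled, and every direction is that of the lungs labelled cGrp78f/f against the control lungs.

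**Figure D1:**
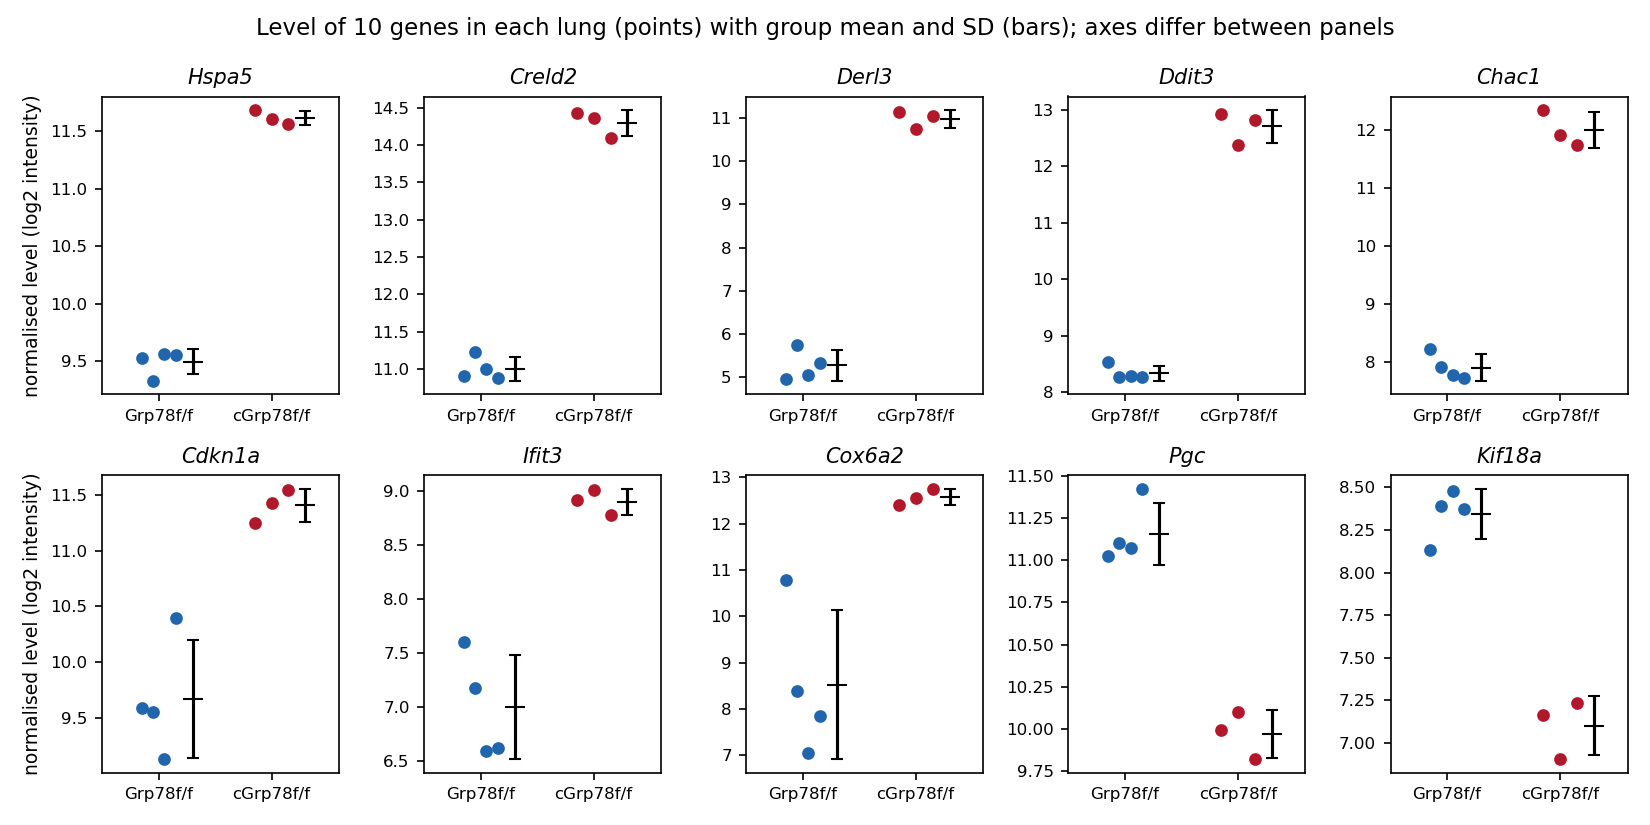
Normalised level (log2 intensity) of 10 genes in each lung, with control lungs labelled Grp78f/f in blue (n = 4) and lungs labelled cGrp78f/f in red (n = 3); black bars give the group mean and SD, and each panel has its own axis. In all 10 panels the groups do not overlap, with Hspa5 at a mean of 9.50 in the control lungs and 11.62 in the lungs labelled cGrp78f/f, while Cox6a2 has a control SD of 1.61.

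With the background correction used here, the largest rise among passing genes in the lungs labelled cGrp78f/f was that of Derl3. Derl3, a component of the machinery that exports misfolded proteins from the ER, rose 52.3-fold, with a log2 difference of 5.71 ± 0.21 (SE). Slc2a6, a hexose transporter of the glucose transporter family, rose 32.2-fold, and Ddit3, which encodes the stress transcription factor CHOP, rose 20.6-fold. Aldh1l2, a mitochondrial enzyme of folate metabolism, rose 19.2-fold, Chac1, which degrades glutathione, 17.1-fold, and Slc7a3, a cationic amino acid transporter, 14.8-fold. Fgf21, a stress-induced hormone, rose 16.7-fold, Steap1, a membrane protein of the STEAP family, 15.3-fold, and Trib3, a pseudokinase, 12.9-fold. B4galnt2, a glycosyltransferase, and Slc7a11, the cystine transporter, were not above background on any control array and were at least 11.5-fold and at least 12.8-fold higher. Of the other genes named here, Derl3, Fgf21 and Steap1 were detected in 1 of the 4 control lungs, Slc2a6 in 2 and Trib3 in 3. Cox6a2, a muscle form of a cytochrome c oxidase subunit, was 16.6-fold higher (log2 difference 4.05 ± 0.75, adjusted p = 0.0318), with control lungs between 7.05 and 10.78. With the mean level of heart muscle genes as a covariate, chosen after the data were seen, it was 5.19-fold higher and did not pass (adjusted p = 0.176, range over the alternatives 0.000403 to 0.176); that level was higher by 1.47 in the lungs labelled cGrp78f/f. The size of rises from dim control levels depended on the processing. The authors' value table is log2-like, and its exact transform is not given. There the difference of Derl3 was 2.82, of Slc2a6 2.38, of Aldh1l2 2.83 and of Slc7a3 2.33. The difference was 1.63 for Trib3, 1.53 for Fgf21 and 1.42 for Steap1. For B4galnt2 it was 1.44 and for Slc7a11 1.52 there, so the bounds given above hold only for the background correction used here. All 9 of these genes passed in every alternative that measured them. Over all alternatives the log2 difference was at least 3.65 for Ddit3 and at least 3.14 for Chac1. Both were therefore above Derl3 in the authors' value table.

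In limma, 289 of 11035 tested genes passed an adjusted p of 0.05, 238 higher and 51 lower. At an unadjusted p under 0.05 the directions were close to balanced, with 981 higher and 1050 lower. The groups did not overlap for any of the 289, and for 18.5% of all tested genes, where chance gives 5.71%. Of the changed genes, 154 changed at least 2-fold (138 higher and 16 lower), and 44 rose and 1 fell at least 4-fold. Of the 238, 24 were not above background on any control array. The 11 other genes of the 12 largest rises passed without each lung in turn, and Cox6a2 did not pass in 6 of the 7 omissions (adjusted p up to 0.120). The count of changed genes was 365 without control lung 2, 162 without control lung 12, 188 without 7-2 and 192 without 7-1, and 154, 152 and 142 without lungs 5, 4 and 6 labelled cGrp78f/f. It was 117 without both control lungs numbered 7, 134 without the pair of lungs with the highest Nppa, and 85 with the mean level of 15 heart muscle genes as a covariate, all chosen after the data were seen.

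**Figure D2:**
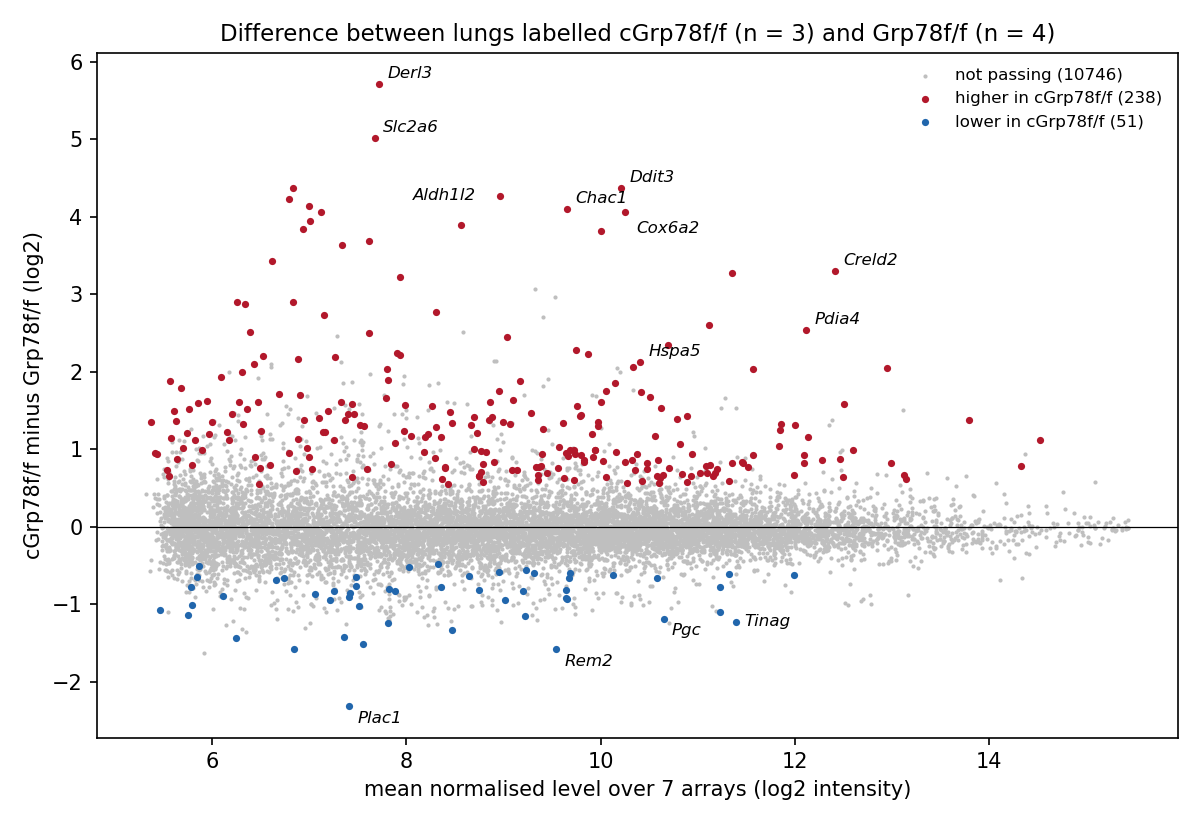
Log2 difference between lungs labelled cGrp78f/f (n = 3) and control lungs (n = 4), on the vertical axis, against the mean normalised level over the 7 arrays (log2 intensity), on the horizontal axis, with each point a tested gene; red and blue points passed an adjusted p of 0.05 and grey points did not. The 238 red points reach 5.71 for Derl3, while the 51 blue points reach -2.32 for Plac1.

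ER chaperones and folding enzymes rose together in the lungs labelled cGrp78f/f. Of 20 tested members of the list, which leaves out Hspa5, 14 rose and 6 did not pass. The largest rises were those of Creld2, a disulphide isomerase-like protein, at 9.80-fold, and of Fkbp11, a prolyl isomerase, at 9.64-fold (log2 level 13.22 ± 0.11, SD, n = 3, against 9.95 ± 0.14, SD, n = 4). Hyou1, an ER chaperone of the Hsp110 type, rose by 2.77 on the log2 scale, Pdia4, a disulphide isomerase, by 2.54 ± 0.12 (SE), and Ero1b, which reoxidises disulphide isomerases, by 2.45 ± 0.14. Hsp90b1, which encodes GRP94, rose by 1.12 and Calr, calreticulin, by 1.25. Pdia3, chosen like Hyou1, Hsp90b1 and Calr after its values were seen, had a log2 difference of 1.51 that did not pass (adjusted p = 0.125). The number that rose was 17 adjusted over the list alone. The list's median difference was 1.28, with a camera adjusted p of 4.11e-25 and of 0.00647 with an estimated correlation, and limma called 0 members lower, also 0 at an unadjusted p under 0.05. Without lung 5 or lung 6 labelled cGrp78f/f, 9 members passed, and 9 passed with the heart muscle covariate.

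Genes of ER-associated degradation and targets of the transcription factor XBP1 also rose. Of 22 tested members, 14 rose and 8 did not pass, and all 22 had a positive difference. Beside Derl3, Sel1l rose 4.12-fold and Syvn1 3.01-fold (log2 differences of 2.04 ± 0.12 and 1.59 ± 0.15, SE); their products form the core of a ubiquitin ligase of the ER membrane. Serp1, a stabiliser of newly made membrane proteins, rose 2.23-fold. Xbp1 itself, chosen after its values were seen, had a difference of 0.19 that did not pass (adjusted p = 0.482); the array measures total transcript, not its splicing. There were 16 that rose adjusted over the list alone. The median difference was 0.84 (camera adjusted p = 2.10e-21, and adjusted p = 0.00617 with an estimated correlation), and limma called 0 members lower, also 0 at an unadjusted p under 0.05. Without lung 5 labelled cGrp78f/f 9 members passed, 8 passed without both control lungs numbered 7, 8 without the pair of lungs with the highest Nppa and 7 with the heart muscle covariate.

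Targets of the transcription factors ATF4 and CHOP, which act when translation is slowed under stress, formed the third list that rose. Of 33 tested members, 20 rose and 13 did not pass. Ddit3 went from a log2 level of 8.33 ± 0.13 (SD, n = 4) to 12.70 ± 0.29 (SD, n = 3), and Chac1, Fgf21 and Slc7a3 rose by 4.09 ± 0.18, 4.06 ± 0.22 and 3.89 ± 0.21 (SE) on the log2 scale. Further members that rose, chosen after their values were seen, were Atf3, a stress transcription factor detected in 2 of the 4 control lungs, by 3.63, Asns, asparagine synthetase, by 2.61, Ppp1r15a, which restores translation after stress, by 2.28, and Phgdh, the first enzyme of serine synthesis, by 1.66. Atf4 itself had a difference of 0.88 that did not pass (adjusted p = 0.0625). Adjusted over the list alone, 27 members rose. The median difference was 1.34 (camera adjusted p = 3.29e-34, and adjusted p = 0.00179 with an estimated correlation), and limma called 0 members lower, also 0 at an unadjusted p under 0.05; in the authors' value table the median was 0.78. Of the 23 lists tested, these 3 were also the ones that passed with an estimated correlation, and the same 3 passed in fry.

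**Figure D3:**
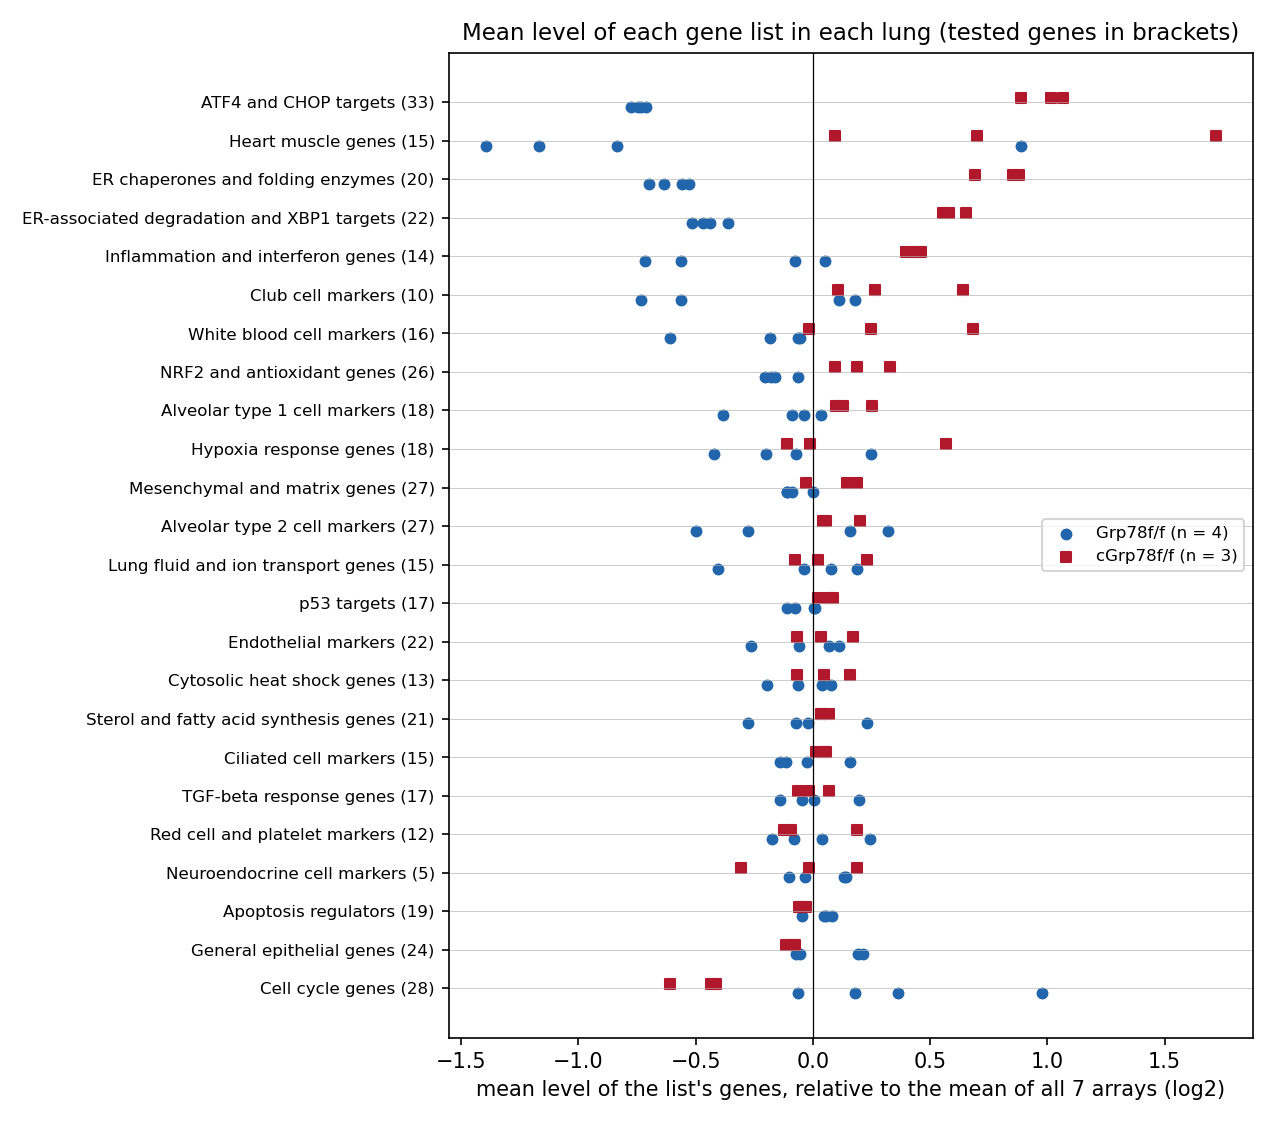
Mean level of the tested genes of each list in each lung, relative to the mean of all 7 arrays (log2, horizontal axis), with control lungs as blue circles (n = 4) and lungs labelled cGrp78f/f as red squares (n = 3); the number of tested genes stands beside each list. For ATF4 and CHOP targets the lungs labelled cGrp78f/f lie between 0.89 and 1.07 and the control lungs between -0.78 and -0.71, while the alveolar type 2 list overlaps between the groups; the heart muscle genes were chosen after the data were seen.

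Of the genes that passed, 51 fell. Plac1, a gene best known from placenta, fell by 2.32 ± 0.40 (SE) on the log2 scale, or 4.98-fold lower, and was detected in 2 of the 3 lungs labelled cGrp78f/f. Rem2, a small GTPase, fell 2.99-fold, Vwa2, a matrix protein, 2.98-fold, Prnd, a relative of the prion protein, 2.84-fold, Acaa1b, a peroxisomal thiolase, 2.69-fold, and Lor, loricrin of the epidermal envelope, 2.68-fold; Vwa2 was detected in 2 and Acaa1b in 1 of those 3 lungs. Pgc, progastricsin, which is made by alveolar type 2 cells and the stomach, fell 2.27-fold, from a log2 level of 11.16 ± 0.18 (SD, n = 4) to 9.97 ± 0.14 (SD, n = 3), and Tinag, a basement membrane protein, fell 2.33-fold. The remaining 4 of the 12 largest falls were genes of chromosome segregation and cell division. Esco2, which joins sister chromatids, fell 2.52-fold, the kinesins Kif18a and Kif18b 2.37-fold and 2.21-fold, and Cks2, a partner of cyclin-dependent kinases, was lower by at least 0.59 on the log2 scale, being not above background on any array labelled cGrp78f/f; that bound holds only for the background correction used here, without which the difference was -0.20 and did not pass. In the authors' log2-like value table the difference was -0.78 for Plac1, -1.11 for Rem2, -0.41 for Vwa2, -0.54 for Prnd and -0.28 for Acaa1b. It was -0.45 for Lor, -0.70 for Esco2, -0.50 for Kif18a and -0.76 for Kif18b, while Pgc (-1.04) and Tinag (-1.16) moved little. Of these, Vwa2, Prnd, Acaa1b, Esco2 and Kif18b did not pass there, and neither did Cks2. Of the 12, Kif18a (adjusted p = 0.00212), Tinag (0.00638) and Pgc (0.00316) passed without each lung in turn, and the other 9 lost the call in at least 4 of the 7 omissions, Prnd in all 7 (adjusted p up to 0.158, for Kif18b). The count of genes that fell was 81 without control lung 2, 13, 25 and 18 without control lungs 12, 7-2 and 7-1, and 17, 9 and 9 without lungs 5, 4 and 6 labelled cGrp78f/f. It was 6 without both control lungs numbered 7, 6 without the pair of lungs with the highest Nppa, and 0 in limma with the heart muscle covariate, where 331 genes were lower at an unadjusted p under 0.05.

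All 28 tested cell cycle genes had lower mean levels in the lungs labelled cGrp78f/f, but 0 passed over all genes. The differences closest to passing were those of Ube2c (-0.92 ± 0.20, SE), Cdk1 (-1.02 ± 0.23), Birc5 (-0.93 ± 0.21) and Ccne2 (-1.03 ± 0.24), with adjusted p between 0.0624 and 0.0682. Their products drive or oversee passage through the cell cycle. A second tested probe of Cdk1 differed by -0.26. The smallest falls over the alternatives were -0.19 for Ube2c, -0.80 for Cdk1, -0.62 for Birc5 and -0.44 for Ccne2. In limma 26 of the 28 were lower at an unadjusted p under 0.05, and 26 also when adjusted over the list alone. The list's median difference was -0.92 and camera called the list lower (adjusted p = 2.10e-13). The adjusted p was 0.431 with an estimated correlation of 0.696 between its genes, and 0.0731 in fry. Over all genes, 4 members fell without control lung 2 and 2 without control lung 7-2, and 6 with array weights, 4 with trend and robust and 3 with the stricter detection filter. There were 2 that fell with an offset of 50, 2 without background correction, 1 in the authors' value table and 1 with control lungs 7-1 and 7-2 averaged. The median was -0.45 with the heart muscle covariate, -0.49 in the authors' value table and -0.52 without background correction. The mean level of the list was -0.44, -0.41 and -0.61 in lungs 5, 4 and 6 labelled cGrp78f/f, relative to all arrays, and -0.06, 0.36, 0.98 and 0.18 in control lungs 2, 12, 7-2 and 7-1. The mean of the heart muscle genes was 0.09, 0.70 and 1.72 in the first 3 of these lungs and 0.89, -0.83, -1.39 and -1.17 in the control lungs, a difference of 1.47 (exact two-sided permutation p = 0.114).

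Among inflammation and interferon genes, 3 of 14 tested members rose and 11 did not pass. Ifit3 rose 3.73-fold (log2 difference 1.90 ± 0.25, SE, adjusted p = 0.00594), Isg15 2.83-fold and Irf7 2.74-fold, all of which are genes induced by interferon; Irf7 was detected in 2 of the 4 control lungs. Rsad2, another interferon-induced gene, had a difference of 2.14 ± 0.48 that did not pass (adjusted p = 0.0633). Adjusted over the list alone, 5 rose. The list passed in camera (median 0.42, adjusted p = 0.000145) but not with an estimated correlation (adjusted p = 0.393). Its median was 0.71 without control lung 12, 0.63 without lung 4 labelled cGrp78f/f and 0.21 without background correction. Ifit3 passed without each lung in turn, while Isg15 did not pass without control lungs 12, 7-2 or 7-1 or lung 6 labelled cGrp78f/f (adjusted p up to 0.0735), and Irf7, among the single omissions, passed only without control lung 2 (adjusted p up to 0.135 otherwise). Over all alternatives Isg15 passed in 13 of 22 and Irf7 in 10 of 21. The number that passed was 5 without control lung 2, 1 without control lung 12, 7-2 or 7-1 or lung 6 labelled cGrp78f/f, and 1 without both control lungs numbered 7; with the heart muscle covariate limma called 0. In the authors' log2-like value table the differences were 0.83 for Ifit3, which passed, and 0.51 for Isg15 and 0.30 for Irf7, which did not.

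Of 16 tested white blood cell markers 2 rose and 14 did not pass. Cd74, the invariant chain of antigen-presenting cells, rose 2.89-fold (1.53 ± 0.31, adjusted p = 0.0431), and C1qa, a complement gene of macrophages, 1.56-fold (0.64 ± 0.13, adjusted p = 0.0493). C1qb had a difference of 0.77 and Ltf of 1.42, neither of which passed. With p adjusted over the list alone, 3 rose. The list passed in camera (median 0.44, adjusted p = 0.000145) but not with an estimated correlation (adjusted p = 0.437). The median was 0.19 without lung 4 labelled cGrp78f/f, in which the list's mean level was 0.68 relative to all arrays, against 0.25 and -0.02 in lungs 5 and 6 of that group and -0.06, -0.06, -0.61 and -0.18 in control lungs 2, 12, 7-2 and 7-1. It was 0.27 without both control lungs numbered 7 and 0.24 in the authors' value table. Cd74 and C1qa passed with all 7 lungs and without control lung 2, but with any other lung left out neither passed (adjusted p up to 0.133 and 0.145); in the authors' value table C1qa differed by 0.23 and did not pass. Over all alternatives Cd74 passed in 10 and C1qa in 4 of 22.

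Of 19 tested apoptosis regulators limma called 0, and 1, Xiap, was lower at an unadjusted p under 0.05. Xiap, an inhibitor of caspases, had a difference of -0.42 ± 0.15 (SE), Bid of -0.24, Fas of 0.41 and Htra2 of 0.33. The list had a median of -0.05 and did not pass (camera adjusted p = 0.445). It holds both promoters and inhibitors of apoptosis, so its median and camera, which look for a shift in 1 direction, could miss a change. Among 17 tested p53 targets, Cdkn1a, which encodes the cell cycle inhibitor p21, rose 3.34-fold (1.74 ± 0.27, adjusted p = 0.0145) and Ccng1, cyclin G1, 1.61-fold (0.68 ± 0.12, adjusted p = 0.0239), and 15 did not pass, among them Gtse1 (-0.88) and Plk2 (-0.34). Adjusted over the list alone, 2 rose and 1 fell. The p53 list did not pass (median 0.06, camera adjusted p = 0.313). Cdkn1a did not pass without control lung 12 (adjusted p = 0.0519) or lungs 4 (0.0673) or 6 (0.0709) labelled cGrp78f/f, without the pair of lungs with the highest Nppa (0.111) or with the heart muscle covariate (0.185), and it passed in 17 of 22 alternatives. Ccng1 passed in 12 of 22, and of the single omissions only without control lung 2. Of 26 tested NRF2 and antioxidant genes 1 rose, Slc7a11, which is also an ATF4 target. Sqstm1 (0.43 ± 0.10), Mt2 (1.17 ± 0.32, detected in 3 control lungs) and Gstm1 (0.53 ± 0.17, with a second probe of the opposite sign) did not pass. Adjusted over the list alone, 2 rose. The list passed in camera (median 0.11, adjusted p = 0.00864), not with an estimated correlation (adjusted p = 0.433) and not without lung 4 labelled cGrp78f/f (median 0.06, adjusted p = 0.0648), with the stricter detection filter (0.0658) or with the heart muscle covariate (0.101).

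No member of the lists of alveolar type 2 and type 1 cell markers passed gene by gene; Pgc, described above, is in neither. In limma the test called 0 of 27 tested alveolar type 2 cell markers, with 2 higher and 1 lower at an unadjusted p under 0.05. The surfactant protein gene Sftpb was at a log2 level of 13.76 ± 0.49 (SD, n = 3) against 13.06 ± 0.22 (SD, n = 4), a difference that did not pass (adjusted p = 0.163), and Napsa, a protease that processes surfactant proteins, differed by 0.39 and Egfl6 by -0.62. Sftpc, the most specific surfactant gene, chosen after its values were seen, differed by -0.04. The list did not pass (median 0.23, camera adjusted p = 0.159), although it passed without control lung 2 (adjusted p = 0.00762), without control lung 12 (0.0480) and without the pair of lungs with the highest Nppa (median 0.32, adjusted p = 0.00821). Its median was -0.01 without control lung 7-2 (0.801), 0.10 without 7-1 (0.406), -0.13 without both (0.165), 0.06 with both averaged (0.582) and 0.15 without lung 4 labelled cGrp78f/f (0.394). It was -0.14 with the heart muscle covariate (0.315), 0.13 with array position (0.314) and 0.09 with array weights. Of 18 tested alveolar type 1 cell markers limma called 0, with 5 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone; Col4a4, a basement membrane collagen chain, came closest (0.83 ± 0.18, adjusted p = 0.0535), before Cyp4b1 (0.89) and Col4a3 (0.63). That list passed in camera (median 0.16, adjusted p = 0.00864) but not with an estimated correlation (adjusted p = 0.580), nor without lung 4 labelled cGrp78f/f (0.0563), nor with the heart muscle covariate (0.0565), and its median was 0.08 without control lung 7-2.

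Among 24 tested general epithelial genes, Cdh16, a kidney and thyroid type cadherin, fell 2.14-fold (-1.10 ± 0.20, SE, adjusted p = 0.0316), also when adjusted over the list alone, and 23 did not pass. Shh, a signal of the growing airway tips, differed by -0.70 ± 0.19, the transcription factor Foxa2 by -0.51 and Elf5 by -0.41. Cdh16 passed with all lungs and without control lung 2, and with any other lung left out it did not (adjusted p up to 0.117); it passed in 11 of 22 alternatives. The list did not pass (median -0.11, camera adjusted p = 0.213). Of 10 tested club cell markers limma called 0, with 3 higher and 1 lower at an unadjusted p under 0.05; the secretoglobins Scgb3a1 (2.97 ± 0.96, adjusted p = 0.157, detected in 3 control lungs) and Scgb1a1 (0.94 ± 0.38) varied widely between control lungs, and Gabrp differed by 1.08. The club cell list passed in camera (median 0.41, adjusted p = 0.0325) but not with an estimated correlation (adjusted p = 0.580). It did not pass without lung 4 labelled cGrp78f/f (median 0.23, adjusted p = 0.123) or without control lung 7-2 (0.30 and 0.0955) or 7-1 (0.26 and 0.0832), nor without both (0.03 and 0.381) or with the heart muscle covariate (0.16 and 0.419), nor with 7-1 and 7-2 averaged (0.0956), the stricter detection filter (0.0658) or sex as a covariate (0.0539). Its mean level was -0.56 and -0.73 in those control lungs against 0.11 and 0.18 in the others. Limma called 0 of 15 ciliated cell markers (2 higher and 1 lower at an unadjusted p under 0.05), among them Foxj1 at -0.41 and Tppp3 at 0.34, and 0 of 5 neuroendocrine markers (1 lower, Cplx2 at -1.06, detected in 2 of the 3 lungs labelled cGrp78f/f). Neither list passed (camera adjusted p of 0.612 and 0.707), and in each the median and the mean differed in sign.

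Outside the epithelium, endothelial markers did not differ by a passing amount, with 0 of 22 called in limma and 2 higher at an unadjusted p under 0.05, Vwf at 0.56 ± 0.17 (SE) and Car4 at 1.82 ± 0.76. Of 27 tested mesenchymal and matrix genes limma called 0, with 3 higher and 1 lower at an unadjusted p under 0.05: the small proteoglycans Lum (1.58 ± 0.41) and Dcn (0.74 ± 0.20), Des (0.68) and Wnt2 (-0.41). The mesenchymal list passed in camera (median 0.15, adjusted p = 0.0325), not with an estimated correlation (adjusted p = 0.431), and not without control lungs 2 (0.0957) or 12 (0.0524, with a median of 0.09) or lungs 4 (0.0676) or 6 (0.147) labelled cGrp78f/f, without the pair of lungs with the highest Nppa (0.218) or with the heart muscle covariate (0.0565). Of 12 red cell and platelet markers limma called 0, with 1 higher and 2 lower at an unadjusted p under 0.05; Tfrc, the transferrin receptor, which dividing cells also make, differed by -1.09 ± 0.24 (adjusted p = 0.0614) and was the 1 gene lower over the list alone. The endothelial and red cell lists did not pass (camera adjusted p of 0.615 and 0.724), and the median and mean of the red cell list differed in sign.

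Among 21 tested genes of sterol and fatty acid synthesis, Mvd rose 2.56-fold (1.36 ± 0.22, SE) and Lss 1.78-fold (0.83 ± 0.16), both enzymes of the cholesterol pathway, and 19 did not pass, among them Me1 (0.50) and Stard4 (-0.46). Adjusted over the list alone, 2 rose. Mvd did not pass without control lung 7-2 or any of the lungs labelled cGrp78f/f (adjusted p up to 0.0829), and Lss, among the single omissions, passed only without lung 4 labelled cGrp78f/f (up to 0.119 otherwise). Over all alternatives Mvd passed in 15 and Lss in 10 of 22. The list did not pass (camera adjusted p = 0.540). Limma called 0 of 17 TGF-beta response genes (1 higher and 3 lower at an unadjusted p under 0.05), with Snai1 at -0.36 and Tgfb2 at -0.54, and 0 of 15 genes of lung fluid and ion transport (3 higher and 1 lower), with the chloride channel Cftr at -0.74 ± 0.21 and the sodium channel subunits Scnn1g at 0.52 and Scnn1a at 0.37. Limma called 0 of 18 hypoxia response genes (2 higher at an unadjusted p under 0.05), with Hk2 at 0.62 and Adm, detected in 3 control lungs, at 0.95, and 0 of 13 cytosolic heat shock genes (1 higher), with Hspb8 at 0.61 and Hspb1 at 0.31. The camera adjusted p was 0.593 for TGF-beta response, 0.593 for ion transport, 0.0502 for hypoxia and 0.615 for heat shock genes, and the median and mean of the heat shock list differed in sign. The hypoxia list passed with an offset of 50 (adjusted p = 0.0420), median scaling (0.0324), no filter on dim probes (0.0281), control lungs 7-1 and 7-2 averaged (0.0205) or left out (0.00396), and array position (0.00807) or sex (0.0168) as a covariate. Its median was 0.12 without background correction and 0.11 in the authors' value table, where it did not pass. It passed without lung 5 (0.0162) or lung 4 (0.00143, with a median of 0.47) labelled cGrp78f/f or control lung 7-1 (0.00416), but its median of 0.29 was 0.04 without lung 6 labelled cGrp78f/f (0.793), 0.02 without the pair of lungs with the highest Nppa (0.742), 0.14 with the heart muscle covariate (0.617) and 0.14 without control lung 12 (0.259). Its mean level was 0.57 in lung 6 labelled cGrp78f/f against -0.01 and -0.11 in the other lungs of that group.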

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

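The tests of explanations for Hspa5, Cox6a2 and the cell cycle list in this part were chosen only after the result was seen. In 4 of 114 results, 1 of the 4 control lungs lay far from the other 3, which chance alone gives in about 1 of 20 groups. Hspa5 was at a log2 level of 9.33 in control lung 12, against 9.53 to 9.56 in the other control lungs. Ddit3 was at 8.53 in control lung 2, against 8.26 to 8.28. Prnd was at 8.90 in control lung 7-2, against 7.89 to 8.02. Bid was at 7.98 in control lung 7-1, against 8.17 to 8.18.

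The Hspa5 probe was higher on the arrays labelled cGrp78f/f, where a knockout label names its product as the target. An exchange of labels between single lungs of the 2 groups is argued against, since the lowest array labelled cGrp78f/f lay 2.00 above the highest control array on the log2 scale. Background correction and normalisation are argued against as the cause, since the difference was at least 1.83 in each of 5 processing alternatives. A rise shared with the other ER chaperone transcripts may account for it, since Hspa5 stood at percentile 70 among the tested members of that list, a test that could have placed it outside them. An exchange of the group labels as a whole cannot be checked by the only probe, with its difference of 2.12, because its place in the gene is not given. Such an exchange would put the rise of the stress targets of ATF4 and CHOP in lungs without the knockout. That list's mean level was 0.89 to 1.07 in the lungs labelled cGrp78f/f and -0.78 to -0.71 in the control lungs. These values argue against an exchange, but they do not read the deletion itself.

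Cox6a2 was 16.6-fold higher (log2 4.05 ± 0.75, SE) in the lungs labelled cGrp78f/f, and background correction and normalisation are argued against as the cause by a difference of at least 3.25 in 5 processing alternatives. Heart muscle in the lung samples may account for part of it: all 15 tested heart muscle genes had a positive difference, 11 at an unadjusted p under 0.05 in limma and 0 after adjustment, and with their mean level as a covariate Cox6a2 differed by 2.38 ± 0.53, or 5.19-fold, and no longer passed (adjusted p = 0.176, with a range of 0.000403 to 0.176 over the alternatives). In that fit the estimate was smaller, the covariate shares variance with the groups and takes a degree of freedom, and 85 genes passed over all; which of these ended the call was not separated. Without the pair of lungs with the highest Nppa, Cox6a2 differed by 4.72. That value decides nothing about heart muscle, since the remaining lungs still differed in its level. It was 0.09 and 0.70 in lungs 5 and 4 labelled cGrp78f/f, and -0.83, -1.39 and -1.17 in control lungs 12, 7-2 and 7-1. Against heart muscle as the whole cause, control lung 2 had less Cox6a2 than lung 5 labelled cGrp78f/f (10.78 against 12.41). Its heart muscle level was 0.89, against 0.09 in that lung. In lungs 5, 4 and 6 labelled cGrp78f/f, Cox6a2 was 12.41, 12.55 and 12.75 over heart muscle levels of 0.09, 0.70 and 1.72. In the control lungs Cox6a2 ran from 7.05 to 10.78 over heart muscle levels of -1.39 to 0.89. The covariate fit assumes the same slope in both groups. Single lungs exclude nothing, so a difference between the groups stays open beside heart muscle.

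The cell cycle list was lower in the lungs labelled cGrp78f/f, with a median of -0.92. The control lungs numbered 7 are argued against as its only cause, since the median was -0.66 without both. A maturation axis shared by all lungs stays open: the alveolar type 2 list had a median of 0.23 with all lungs and of -0.13 without both those lungs (camera adjusted p = 0.165), but these are the control lungs with the lowest mean level of that list, so leaving them out decides nothing. A chance difference of a single group of genes that vary together between embryos may account for the pattern, since the exact two-sided permutation p of the list's mean level was 0.0571, where the smallest possible was 0.0286. A difference between the labelled groups stays open for the same reason.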

How the results depend on the processing

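The omission of both control lungs numbered 7, the omission of the pair of lungs with the highest Nppa, and the heart muscle covariate were chosen only after the data were seen; the other alternatives and the test over splits were planned. Of the 35 splits of the 7 lungs into groups of 4 and 3, 1, the real one, gave as many as 289 changed genes and the highest other gave 1. A share of 1 in 35 is the smallest that this test can give. The other splits mix the labelled groups, which widens the spread within them and lowers their counts. The test therefore does not exclude chance. Hspa5 passed in every alternative run, with a log2 difference between 1.83 and 2.19. With all probes counted it was tested by the same probe, since the array carries no other for it. All 289 changed genes kept their sign in each alternative that measured them. Their groups did not overlap, so leaving out, averaging or weighting lungs could not change a sign. The trend and robust setting leaves the differences as they are. The sign was at stake mainly under other processing or a covariate. Leaving out each lung gave 142 to 365 changed genes, 133 to 284 higher, 9 to 81 lower, and 7 to 11 passing lists. The number of changed genes was 116 at an adjusted p under 0.01, 192 with sex as a covariate and 491 with array weights. It was 117 without both control lungs numbered 7, 134 without the pair with the highest Nppa and 85 with the heart muscle covariate. Genes higher numbered 111, 111, 128 and 85 at an adjusted p under 0.01, without both lungs numbered 7, without the Nppa pair and with the heart muscle covariate. Genes lower numbered 84 with an offset of 50, 77 without background correction, 81 in the authors' value table, 123 with trend and robust and 157 with array weights. They numbered 24 with array position, 21 with sex, 5 at an adjusted p under 0.01, 6 without both lungs numbered 7, 6 without the Nppa pair, and 0 in limma with the heart muscle covariate, where 331 were lower at an unadjusted p under 0.05. The share higher was 68.0% with array weights and 71.3% with trend and robust, against 82.4%. Passing lists numbered 6 with the heart muscle covariate, 3 with an estimated correlation and 3 in fry, against 10. The smaller p threshold lowers a count by construction. Fewer arrays need not, since the count of changed genes was 365 without control lung 2. For the settings other than the p threshold the cause was not tested. Over 22 alternatives the 41 passing named genes other than Hspa5 kept the call in 676 cases and lost it in 212, with 57 calls gained and 0 reversed, and 18 kept it in every alternative. Over 24 alternatives the 10 passing lists kept the call in 207 cases and lost it in 33, with 13 gained and 0 reversed, and 3 kept it in every alternative: the ER chaperone, ER-associated degradation and ATF4 lists. Array weights and the trend and robust setting do not enter camera. The list calls were therefore fixed under those settings, and the kept cases there test nothing. Signal over background limits the folds of the 24 genes that rose from undetected control levels, which are lower bounds under the background correction used; without it the differences of B4galnt2 and Slc7a11 were 1.65 and 1.77.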

Other observations

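The gene families in this part, and their tests, were chosen only after the result was seen. Of 21 tested subunits of the translocon, signal recognition and signal peptidase complexes, which move new proteins into the ER, 6 rose in the lungs labelled cGrp78f/f, among them Sec11c (0.94 ± 0.14, SE, log2), Sec61a1 (0.86 ± 0.13) and Sec63 (0.75 ± 0.12). The family's median was 0.34 (camera adjusted p = 2.15e-06, and adjusted p = 0.0537 with an estimated correlation). Of 16 cytosolic aminoacyl-tRNA synthetases, which load amino acids on tRNA, 5 rose, led by Wars (1.39 ± 0.14) and Eprs (0.93 ± 0.12), with a median of 0.46 (4.60e-06, and adjusted p = 0.233 with an estimated correlation), while limma called 0 of 11 mitochondrial ones (1 higher and 1 lower at an unadjusted p under 0.05). These families share genes with the lists above. Of the genes that rose, Eprs, Nars and Sars are also in the ATF4 and CHOP list. Sec61a1 and Spcs3 are also in the ER-associated degradation list. Of 32 genes of N-glycan assembly 3 rose, Uggt1 (0.93), Alg12 (0.86) and Gmppb (1.12), and of 32 coat and cargo receptor genes of transport between ER and Golgi 4 rose, led by Mcfd2 (1.31 ± 0.11). Their camera adjusted p were 7.98e-05 and 0.000140, and each had an adjusted p = 0.292 with an estimated correlation. Of 16 Slc35 nucleotide sugar transporters 2 rose, Slc35b1 (0.87) and Slc35c1 (0.79), with a family adjusted p of 0.357. Bhlha15, a transcription factor of secretory cells, rose 9.32-fold and Gadd45a, a stress-induced growth arrest gene, 3.05-fold.

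Among families outside the secretory pathway, 2 of 15 MHC class I and II genes rose, H2-T23 (1.27 ± 0.22) and H2-Q7 (0.75 ± 0.14), with a median of 0.58 (0.000164, and adjusted p = 0.292 with an estimated correlation). Of 13 keratins 2 rose, Krt17, of stressed and basal epithelium, by 2.87 ± 0.26 (detected in 1 of the 4 control lungs) and Krt80 by 0.76, with a family adjusted p of 0.0150, and adjusted p = 0.205 with an estimated correlation. Of 12 serpins 3 rose, Serpinf1 (0.93), Serpina3n (3.04-fold, detected in 1 control lung) and Serpinb3a (at least 1.65-fold, detected in 0 control lungs), with 0.000652, and adjusted p = 0.205 with an estimated correlation. Of 19 kinesins 2 fell, Kif18a and Kif18b, with a median of -0.34 (0.000652, and adjusted p = 0.292 with an estimated correlation). Limma called 0 of 39 histone genes, of which 4 had a positive difference and 13 were lower at an unadjusted p under 0.05, with a median of -0.46 (4.60e-06, and adjusted p = 0.334 with an estimated correlation). Of 30 collagens 1 rose, Col26a1 (1.17 ± 0.18), of 34 proteasome subunits 1 fell, Psmd6 (-0.52 ± 0.11), and of 72 respiratory chain subunits 1 rose, Cox6a2, with family adjusted p of 0.186, 0.155 and 0.167. Limma called 0 of 53 cytosolic ribosomal protein genes (1 lower at an unadjusted p under 0.05, family adjusted p of 0.418) and 0 of 67 mitochondrial ones (1 higher and 6 lower, 0.0390, and adjusted p = 0.630 with an estimated correlation). Each family's median kept its sign under the processing alternatives, but its size depended on them: the lowest median was 0.14 for MHC genes, and the one nearest to 0 for histones was -0.13.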
